A study of Mus musculus with 4 samples.

How the data were processed

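Nuclei were isolated from brain tissue of 2-month-old C57BL/6 mice, wild type or homozygous for a single-base coding substitution in Wdr4 made by CRISPR-Cas9, and libraries were made with the 10x 3' v3.1 kit, 2 per genotype. The deposited files hold 1 matrix of UMI counts per library, raw and not normalized per the file headers, with the barcodes that the authors called. The matrix headers name Cell Ranger 5.0.0, while the submitters' processing notes name Cell Ranger 3.1.0, Seurat and mm10. Whether intronic reads were counted, the Seurat version, the part of the brain taken and whether replicates were separate animals are not given in the sources used here. Since strand and intron counting are not stated, values of overlapping or antisense genes such as Pip5k1bos are uncertain. The matrices hold 9225, 10176, 14150 and 9095 barcodes and 35220112, 47902579, 84116422 and 32981791 UMIs (wild type 1, wild type 2, mKI 1, mKI 2), and all 4 libraries share 27998 genes. Of the gene IDs, 27645 (98.7%) were found in GENCODE vM21 (GRCm38, the same build as mm10), from which coordinates were taken, and 121 matrix lines share a symbol with another and were kept apart by gene ID.

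Nuclei with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs were kept (268, 229, 13 and 398 barcodes removed). Doublet scores came from Scrublet in scanpy 1.11.5, run per library. Its automatic threshold marked 0, 0, 985 and 1 nuclei, so the 6% of nuclei with the highest score were removed from each library (504, 571, 823 and 493), a rule set after seeing the scores. Counts were scaled to 10000 per nucleus and log-transformed, 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 0) were used, and no integration across libraries was done. Each of the 36 clusters took the class of the 28 marker lists with the highest score, the mean log2 of CPM plus 10 over the median cluster. A cluster stayed unnamed if that score was under 1.0, if fewer than 3 markers were detected at 20 CPM, if its median doublet score was over 0.1, or if its top 10 genes held more markers of another class than of its own. With no own marker among those 10, it also stayed unnamed if under 70% of the markers were detected or if its median UMI count was under 0.33 of the library median. These thresholds were set after seeing the clusters, and 7 stayed unnamed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used, with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (1.17.8).

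Counts were summed per class and library, and the 13 classes with at least 20 nuclei in each library, and all nuclei together, were tested. Wild type was compared with mKI by edgeR quasi-likelihood tests (TMM factors, filterByExpr with a minimum count of 10, no robust dispersion), with Benjamini-Hochberg adjustment within each class at 0.05. CPM printed beside fold changes are scaled by TMM factors, and those of marker groups, hemoglobin and the sex and substrain check genes are not. Standard errors of edgeR values are the absolute log2 fold change over the square root of the quasi-likelihood F statistic. The 29 gene lists were fixed before the data were examined and tested by camera with a preset correlation of 0.01, adjusted over all lists and classes, where at least 5 genes of a list were tested (2 for the methyltransferase list). They cover the m7G methyltransferase (2 of 2 genes matched), tRNA modification (69 of 72), aminoacyl-tRNA synthetases (22 of 40, since both versions of each symbol were listed), translation factors, ribosomal proteins, the integrated stress, unfolded protein, heat shock, interferon, p53 and glucocorticoid responses, oxidative phosphorylation, mitochondrially encoded and immediate early genes, synapses, channels, axon guidance, neurogenesis, cell cycle, myelin, microglial and astrocyte states, cholesterol synthesis, circadian clock, neurotrophins and mTOR. Nuclei per class were tested by edgeR on counts of nuclei with all kept nuclei of a library as its size, and class ratios by exact permutation, in which the smallest possible p is 0.33. The genotype effect was compared between classes by limma on differences of log2 CPM (prior count 2) within libraries.

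Genes were named by a rule fixed before the data were examined. In each tested class these were the 5 called genes with the largest log2 fold change in each direction (10 each in all nuclei) with both mKI libraries on the same side of both wild-type libraries, or, where fewer than 5 passed, the 5 genes with the smallest p as values, and up to 4 called genes per list and class by p. Wdr4 and Mettl1 were always named, and predicted genes with Gm or Rik symbols were passed over. Of the genes that the rule named, 2 are not reported here, though the counts include them. Genes named for the differences between classes and for the unnamed clusters were chosen after their values were seen. Folds against a group with 0 counts are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts a ratio of counts with its counting interval is given. These intervals pool the UMIs of both libraries of a genotype and leave out the spread between libraries. The pairs of wild type 1 and mKI 1 against the others, and the other such split, called 0 genes in every class. Each group there holds 1 library of either genotype, so a genotype difference widens the spread within groups and lowers the calls. These splits therefore do not measure the rate of false calls.

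The scripts were tested on simulated data with the depth and dispersion of each comparison, 200 changed genes each. At 4-fold the share recovered was 64.6% in all nuclei, 74.0% in glutamatergic, 84.5% in dentate granule, 78.8% in cerebellar granule and 84.7% in GABAergic neurons, 84.7% in molecular layer interneurons, 78.0% in astrocytes, 70.2% in Bergmann glia, 83.0% in oligodendrocytes, 87.8% in precursors, 2.06% in microglia, 69.7% in endothelial cells, 70.7% in pericytes and 81.6% in meningeal fibroblasts. At 2-fold it was 4.04, 25.5, 28.0, 15.0, 37.6, 33.7, 11.2, 11.5, 18.6, 36.6, 0, 6.12, 7.37 and 18.1% in the same order. Between 1 and 17 unchanged genes were called per comparison. Of 10 changed lists, camera with the preset correlation recovered 10 in every comparison (1 of 20 unchanged lists was called in astrocytes). With an estimated correlation it recovered 0 in dentate granule neurons, molecular layer interneurons, endothelial cells and pericytes and between 4 and 10 elsewhere. Genes were drawn without correlation between them, and all genes of a changed list moved 2- or 4-fold in 1 direction. These rates therefore do not carry over to lists of correlated genes or with smaller changes. Tests of differences between classes recovered at most 1.56% at 4-fold. A class with 0 calls therefore leaves 2-fold changes mostly unread.

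The alternatives were DESeq2, RLE factors, no low-count filter, counts thinned to the smallest library of a class, replicate number as a block, each library left out, doublets kept, all deposited barcodes, classes by marker score, Leiden resolution 2, an estimated list correlation, a prior count of 0.5 and a minimum count of 30. Chosen after seeing the data were granule cluster 5 alone (its lists also with an estimated correlation), granule clusters 3 and 4 alone, genes with wild-type granule CPM over 3 times that of the class left out, a crossed pairing, granule nuclei left out of the total, unnamed nuclei left out and the granule against glutamatergic pair. Nuclei of unnamed clusters were left out of class tests, and classes with too few nuclei (among them olfactory bulb granule, striatal, thalamic and Purkinje neurons) out of gene tests.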

Results

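Single-nucleus RNA sequencing (10x 3' v3.1) was used to read nuclei from the brains of 2-month-old mice, 2 libraries of wild type and 2 of homozygous Wdr4 knock-in mice (WDR4 mKI), which carry a single-base coding substitution. WDR4 is the partner of METTL1 in the enzyme that places N7-methylguanosine (m7G) on tRNA, so each of 13 cell classes was asked which genes, gene groups and nuclei counts differed with the mutation. All 39347 nuclei kept fell in 36 clusters, of which 29 were named as 18 classes from marker genes. The sources do not state that the replicates were separate animals, so p-values measure only the spread between these samples.

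All 4 libraries came from males: Ddx3y, on the Y chromosome, stood at 60.1, 49.3, 57.1 and 52.5 CPM (order wild type 1, wild type 2, mKI 1, mKI 2, kept for every set of 4 values). Xist, the RNA of the inactive X, stood at 0.249, 0.409, 0.263 and 0.199. Nnt, which separates C57BL/6 substrains, was read in all 4 at 28.1, 31.4, 42.6 and 38.3. Of 10 genes in the substrain and Wdr4 neighbourhood check, Rsph1 had the lowest adjusted p (edgeR, 0.206), and Cryaa had 1 count. The libraries differed in depth: the median was 2559, 3057, 4329.5 and 2277 UMIs per kept nucleus, and the median mitochondrial share was 0.311, 0.215, 0.0691 and 0.596%. Nuclei kept numbered 8453, 9376, 13314 and 8204.

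Mettl1, the catalytic subunit of the m7G methyltransferase, rose 3.16-fold in mKI cerebellar granule neurons (log2 1.66, SE 0.23, edgeR adjusted p = 0.0263, 2 against 2 libraries), from 5.15 and 6.59 to 18.8 and 18.2 CPM. Wdr4 itself (GRCm38/mm10 chr17:31494322-31519980, minus strand) stood at 8.81, 8.74, 16.1 and 14.5 CPM there (log2 0.82, SE 0.20, adjusted p = 0.0870). In all nuclei Wdr4 had log2 0.45 (SE 0.23, adjusted p = 0.393) and Mettl1 (chr10:127041414-127046365, plus strand) 0.82 (SE 0.24, adjusted p = 0.213). The 2-gene methyltransferase list was called higher in granule neurons (median log2 1.24, camera adjusted p = 0.0113; adjusted p = 0.980 with an estimated correlation), and in 0 of 5 other classes. Wdr4 and Mettl1 values were 0.29 and 0.32 in glutamatergic neurons, 0.76 and 1.15 in molecular layer interneurons, 0.47 and 0.67 in astrocytes, 0.03 and 0.56 in oligodendrocytes and -0.09 and -0.15 in GABAergic neurons. Mettl1 stood at 1.41 in dentate granule neurons and -0.52 in microglia. Wdr4 stood at 0.61 in endothelial cells, 0.12 in meningeal fibroblasts and -0.04 in precursors, and none of these passed the threshold. Without mKI 1 and without mKI 2 in turn, Wdr4 was 0.0093 and 1.09 and Mettl1 0.18 and 1.39 in astrocytes, Wdr4 was 0.14 and 0.66 in all nuclei and -0.039 and 0.55 in glutamatergic neurons, and Mettl1 was 0.33 and 0.71 in oligodendrocytes. Wdr4 ranged from 0.56 to 1.27 in molecular layer interneurons, -0.39 to 0.67 in oligodendrocytes and -0.72 to 0.21 in GABAergic neurons, where Mettl1 ranged from -0.77 to 1.73. The granule Mettl1 call was lost without wild type 1 (log2 1.49, adjusted p = 0.236), without wild type 2 (1.84, 0.142), with no low-count filter (1.60, 0.0779) and within granule cluster 5 alone (0.79, 0.849); Wdr4 passed without mKI 2 (0.88, adjusted p = 0.0148). The list call was lost without wild type 1 (adjusted p = 0.06), without mKI 1 (0.18) and in cluster 5 alone (0.25), and since the mutation is 1 base, 3' counts do not read it and the Wdr4 level does not check the labels.

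Cerebellar granule neurons made up 50.2, 38.4, 12.1 and 7.31% of kept nuclei, the largest class in wild type (log2 -2.19, SE 0.81, adjusted p = 0.200). Bergmann glia, the astrocytes of the Purkinje layer, stood at 1.90, 1.57, 0.233 and 0.427% (-2.40, SE 0.83, adjusted p = 0.200), and Purkinje neurons at 0.260, 0.587, 0.0751 and 0.110% (-2.19, SE 0.89, adjusted p = 0.207). Olfactory bulb granule neurons stood at 1.10, 0.128, 4.6 and 11.5% (3.71, SE 1.27, adjusted p = 0.200; 5.96 without wild type 1). Counts of nuclei passed the threshold in 0 of 18 classes (edgeR), with these 4 classes at unadjusted p under 0.05; DESeq2 was not run on nuclei counts. Striatal projection neurons made up 0, 2.09, 6.69 and 5.45%, with 0 of 8453 nuclei in wild type 1 (upper limit 0.0355%). Glutamatergic neurons made up 6.21, 16.8, 24.2 and 23.3%, and GABAergic neurons 0.970, 2.50, 6.68 and 3.80%. Oligodendrocytes stood at 5.69, 5.11, 9.86 and 6.59%, astrocytes at 6.83, 5.77, 1.28 and 8.45%, endothelial cells 4.15, 3.23, 0.481 and 5.47%, and microglia 1.23, 1.34, 3.21 and 2.46%. With nuclei classed by marker score, granule neurons (-3.17, adjusted p = 0.0116) and olfactory bulb granule neurons (2.72, 0.0186) passed, and striatal neurons did without wild type 2 (adjusted p = 0.00551). The parts of the brain that were taken, on which such shares rest, are not given in the sources used here. Unnamed clusters, kept out by thresholds set after seeing the data, held between 0.0505 and 4.89% of wild-type and between 0.177 and 10.8% of mKI nuclei (cluster 11 the largest, 4.89 and 10.8%).

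**Figure D1:**
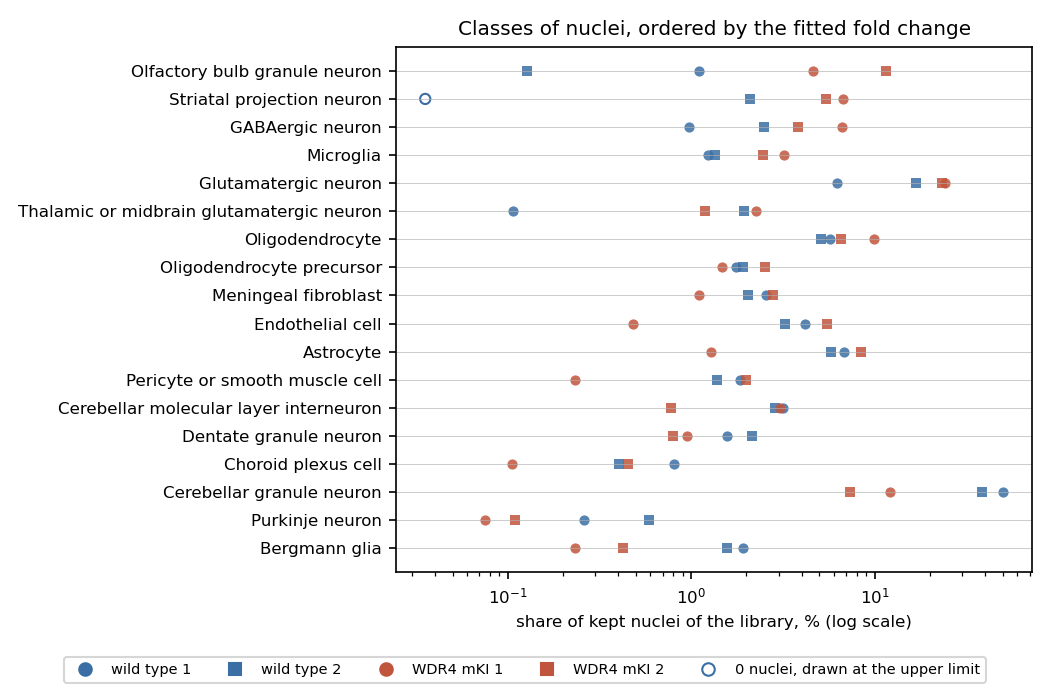
Share of kept nuclei (percent, log axis) of each named class in each of the 4 libraries, wild type and WDR4 mKI coloured separately. Granule, Bergmann and Purkinje points of the mKI libraries lie below those of wild type, and the wild type 1 striatal point is drawn at its upper limit.

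Nuclei named glutamatergic neurons numbered 6.4, 6.73, 3.63 and 6.12 per nucleus named GABAergic neuron (log2 difference -0.48). The exact permutation p was 0.33, the smallest that 2 against 2 libraries can reach, and the difference was -0.10 without mKI 1 and -0.85 without mKI 2. This ratio leaves out unnamed cluster 11, whose highest marker score was GABAergic. That cluster held 432, 440, 1703 and 623 nuclei, against 82, 234, 889 and 312 named GABAergic neurons. Striatal, olfactory bulb granule and Purkinje neurons and molecular layer interneurons were also left out, as classes of their own. Nuclei of the named neuron classes numbered 1.74, 2.07, 1.54 and 1.19 per other nucleus (-0.49, exact permutation p = 0.33). The difference was -0.13 when unnamed nuclei were left out, 0.040 by marker score and -0.30 without mKI 2. Other nuclei here include the unnamed clusters, of which 6, 7, 11, 16 and 24 had their highest marker score in a neuron class. Cluster 11 held 5.11, 4.69, 12.8 and 7.59% of kept nuclei, and cluster 24 held 0.473, 1.85, 4.31 and 2.94%. Oligodendrocytes numbered 3.25, 2.66, 6.73 and 2.61 per precursor (0.51, exact permutation p = 1), with mKI 1 alone above both wild-type libraries and values of -0.17 without it and 1.20 without mKI 2. Since p could not fall below 0.33, no ratio could pass the threshold. As counted here, for glutamatergic to GABAergic neurons and for neurons to other nuclei, both mKI libraries lay below both wild-type libraries. Whether this order holds with the unnamed clusters counted as neurons was not computed.

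Genes of the integrated stress response, the program that ATF4 switches on when translation is slowed, were higher in mKI nuclei in all 12 classes in which the list could be tested (camera, preset correlation 0.01), with a median over classes of 1.16 in log2. The classes share the same libraries, so this and later counts of classes are not independent agreements. Cerebellar granule neurons had the largest median, 2.75 (29 genes, 28 higher in both mKI libraries than in both wild-type libraries, adjusted p = 5.95e-67; adjusted p = 0.723 with an estimated correlation). Molecular layer interneurons had 1.93 (20 genes, adjusted p = 2.19e-33; 0.723 estimated), pericytes 1.89 (18 genes, 2.34e-28; 0.723), and dentate granule neurons 1.70 (13 genes, 6.26e-20; 0.723). Endothelial cells had 1.52 (22 genes, 6.83e-23; 0.980), glutamatergic neurons 1.46 (27 genes, 1.22e-42; 0.968) and GABAergic neurons 0.87 (14 genes, 2.19e-11; 0.723). Smaller medians were found in oligodendrocytes (0.65, adjusted p = 1.60e-05; 0.980 estimated), meningeal fibroblasts (0.61, 3.40e-06; 0.980), astrocytes (0.40, 4.31e-07; 0.980), oligodendrocyte precursors (0.39, 0.0025; 0.980) and microglia (0.38, 0.0270; 0.980). Adjusted over the list alone, 23 genes rose in granule neurons, 19 in glutamatergic neurons, 17 in molecular layer interneurons, 13 each in pericytes and endothelial cells and 10 in dentate granule neurons. On the same footing 7 rose in meningeal fibroblasts (with 1 that fell), 3 in GABAergic neurons, 2 each in astrocytes and oligodendrocytes, and 0 in precursors and microglia. By chance 33.3% of genes separate 2 libraries from 2, in either direction. The call was lost in oligodendrocytes without mKI 2 (median 0.52, adjusted p = 0.15) and in microglia without mKI 1 (0.062, adjusted p = 0.24; 0.91 without wild type 1). Elsewhere medians with 1 library left out ranged from 0.17 to 0.48 in astrocytes, 0.38 to 0.82 in precursors, 0.43 to 0.99 in meningeal fibroblasts, 0.93 to 1.89 in endothelial cells and 1.19 to 1.86 in pericytes, and no list passed in any class with the correlation estimated.

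Each gene was counted over the classes in which it was tested, without the sum of all nuclei. All classes come from the same 4 libraries, so a difference between libraries can recur in each class, and these counts are not independent agreements. Ddit3, the CHOP transcription factor, was higher in both mKI libraries than in both wild-type libraries in 12 of 13 classes. Slc7a1, a cationic amino acid transporter, was so in 12 of 12, and Atf4, the head of the program, in 11 of 12. Cebpg, a dimer partner of ATF4, was higher in 11 of 13, Nupr1, a stress-induced nuclear protein, in 9 of 9, Mthfd2, of mitochondrial folate metabolism, in 9 of 13 and Atf5 in 8 of 9. Asns, which makes asparagine, was higher in 7 of 8, Slc7a3 in 6 of 7, and Trib3, Eif4ebp1 and Sesn2 in 5 of 5 each. Slc3a2 was higher in 7 of 13 and Slc7a5 and Psph in 6 of 12 each. Ddit4 was higher in only 1 of 9 and Psat1, of serine synthesis, in 2 of 7.

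**Figure D2:**
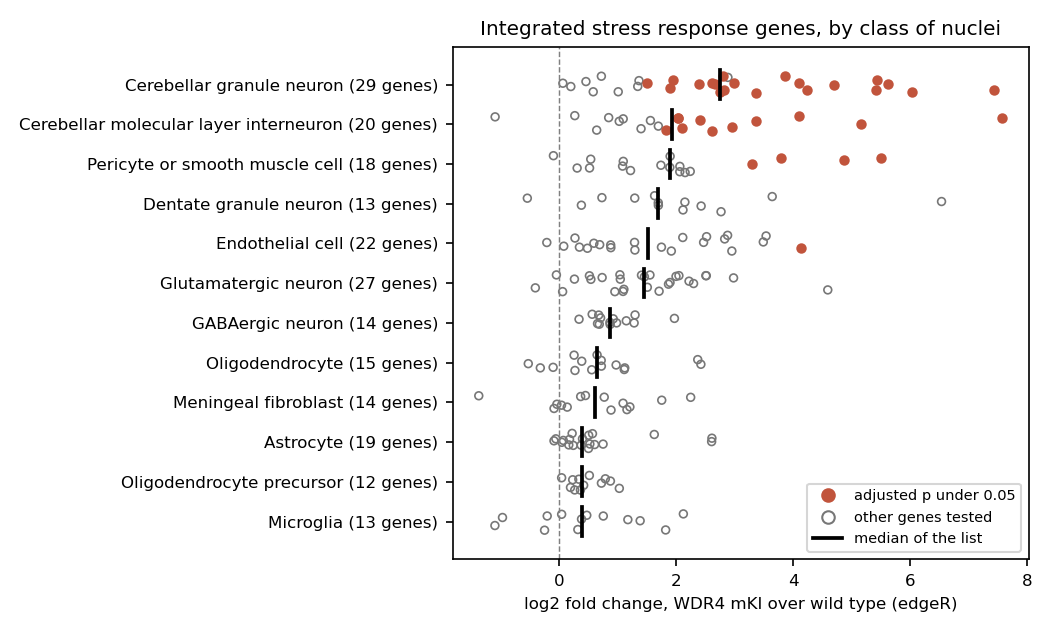
Log2 fold change (mKI over wild type) of each integrated stress response gene in each class, 1 point per gene, red where edgeR adjusted p was under 0.05, bar at the median. Medians lie above 0 in every class shown and are highest in cerebellar granule neurons.

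Aminoacyl-tRNA synthetases, which load amino acids onto tRNA, were higher in 9 of 13 classes (camera). Medians were 0.95 in dentate granule neurons (19 genes, adjusted p = 2.32e-17; adjusted p = 0.723 with an estimated correlation), 0.89 in cerebellar granule neurons (22 genes, all positive, 4.36e-16; 0.723), 0.89 in pericytes (18 genes, 2.14e-09; 0.980) and 0.81 in molecular layer interneurons (20 genes, 1.16e-15; 0.723). They were 0.44 in endothelial cells (1.56e-07; 0.980), 0.44 in meningeal fibroblasts (0.0038; 0.980), 0.34 in GABAergic neurons (3.09e-05; 0.980), 0.31 in glutamatergic neurons (3.13e-10; 0.723) and 0.17 in astrocytes (0.0268; 0.980). Adjusted over the list alone, 12 synthetase genes rose in granule neurons, 11 in molecular layer interneurons, 9 in dentate granule neurons, 8 each in endothelial cells and pericytes, 5 in glutamatergic neurons and 0 in GABAergic neurons, astrocytes and meningeal fibroblasts. Microglia (0.37), oligodendrocyte precursors (0.24), Bergmann glia (0.16) and oligodendrocytes (0.12) were not called. The astrocyte call was lost without wild type 1, wild type 2 or mKI 2 and with doublets kept, and the meningeal call without wild type 1 (adjusted p = 0.061); the GABAergic median ranged from 0.17 to 0.60 and the astrocyte one from 0.083 to 0.28. The other tRNA modification enzymes (median over classes 0.08) and translation initiation and elongation factors (0.06) passed in 0 of 13 classes.

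In cerebellar granule neurons 380 genes rose and 240 fell of 14406 tested (edgeR; DESeq2 called 924, 611 of them in both), and 129 were called with no low-count filter. Fam129a, the stress-induced Niban protein, rose 241-fold (log2 7.91, SE 0.20, adjusted p = 0.00114; 0.474, 0.403, 111 and 107 CPM), Slc7a3, a cationic amino acid transporter, 172-fold (7.43, SE 0.33, 0.00229), and Nupr1 42.5-fold (5.41, SE 0.20, 0.00155). Atf5 rose 18.9-fold (4.24, SE 0.20, 0.00271), Slc7a1 10.3-fold (3.37, SE 0.16, 0.00275), the leucine sensor gene Sesn2 14.5-fold (3.86, SE 0.28, 0.00602) and Eif4ebp1, a brake on cap-dependent translation, 25.9-fold (4.70, SE 0.70, 0.0314). With few wild-type counts, Cyb5r2, a cytochrome b5 reductase, had a count ratio of 242 (interval 65.1 to 2030), Soat2, which esterifies cholesterol, 109 (28.3 to 931) and Stc2, a secreted stress-induced glycoprotein, 101 (16.1 to 4201). Synthetase genes rose: Cars 5.15-fold (2.37, SE 0.15, 0.00462), Iars 3.62-fold, Aars 3.56-fold and Gars 3.26-fold, 10 of 22 past the threshold. Trmt61a, which methylates position 58 of tRNA, rose 7.17-fold (2.84, SE 0.39, 0.0256). The granule nuclei of the 2 genotypes lay in different clusters: clusters 3 and 4 held 68.3 and 29.9% of wild-type and 3.66 and 0.271% of mKI granule nuclei, and cluster 5 held 1.72 and 96.1%. Of 62 named genes, 36 lost the call without wild type 1 (adjusted p up to 0.569), 40 without wild type 2 (up to 0.521), 1 without mKI 1 (0.0646), 36 with no low-count filter and 41 of 48 in cluster 5 alone, of which 2 turned. Without wild type 1 and without wild type 2 in turn, log2 values moved to 6.77 and 3.89 for Eif4ebp1 and 8.24 and 6.89 for Slc7a3. Soat2 was 5.65 without wild type 1, which had 0 counts, and Stc2 5.19 without wild type 2, which had 0. The genes called were 139, 115, 2412 and 3825 with each library left out in turn.

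**Figure D3:**
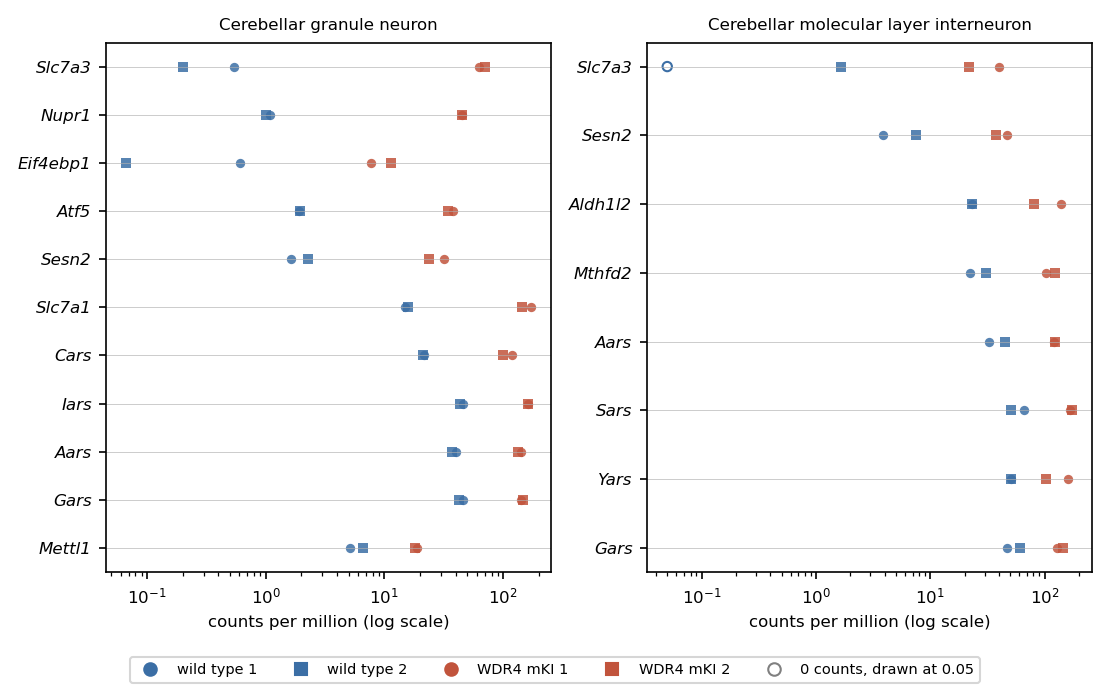
CPM (log axis) in each library of the named stress response, synthetase, mTOR and methyltransferase genes that passed the threshold, granule neurons on the left and molecular layer interneurons on the right. Open symbols mark libraries with 0 counts, and mKI points lie above wild-type points for every gene drawn.

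Genes of synapses and excitability changed in both directions in mKI granule neurons. Rises were seen in Cacng3, an AMPA receptor auxiliary subunit (11.6-fold, log2 3.53, SE 0.19, adjusted p = 0.00324), Unc13b, which primes vesicles (6.93-fold), the potassium channel gene Kcnb2 (5.53-fold) and Cacna2d3 (1.37). Dlg2 (0.99), Gabra5 (1.93) and Slc32a1, the vesicular GABA transporter (1.44), rose as well. Falls were seen in the AMPA receptor gene Gria4 (-1.16, SE 0.11, 0.00942), Dlg1 (-0.76), Gabra6, the granule-cell GABA receptor subunit (-1.45; 769, 888, 267 and 341 CPM) and Gabrb2 (-0.92). The release genes Rims2 (-1.08), Rims1 (-0.61) and Syt1 (-0.84) and the channel gene Kcna1 (-1.21) fell too. Dscam, a cell adhesion gene, rose 4.48-fold, while the guidance genes Ntng1 (-1.65), Epha3 (-1.29) and Plxna4 (-1.46) fell. Of the cell cycle list Ccnd2, cyclin D2, rose (24.4-fold, 4.61, SE 0.18, 0.00155). Of the neurogenesis list Sox11 (3.14) and Dlx1 (2.79) rose and Neurod1 (-1.25) fell. Bdnf rose 4.15-fold (2.05, SE 0.16, 0.00694) and Ntf3 by 2.26 in log2, and Igf2r fell (-1.19). Among immediate early genes Jun fell (-1.80) while Npas4 (2.82) and Nr4a1 (1.83) rose. The clock genes Npas2 (2.31) and Ciart (1.23) rose while Tef fell (-0.95). Herpud1 (1.20), Ern1 (0.87), the p53 target Bbc3 (1.57), Cldn11 (1.45), Klf15 (1.93) and Tsc22d3 (1.64) rose, and Hspa4l (-0.80) and the sterol carrier gene Stard4 (-1.5) fell. The 5 largest falls were Emilin3, a matrix glycoprotein (ratio 0.0337, interval 0.000847 to 0.190), Col27a1 (-4.23, SE 0.71, 0.0414), Tgm5 (0.0633, 0.00761 to 0.232), Chst7 (0.0744, 0.00893 to 0.274) and the RNA Dnm3os (-3.65, SE 0.56, 0.0331). In 20 of the 62 the call held without each library in turn (among them Atf5, Bdnf, Cacng3, Cars, Ccnd2, Cyb5r2, Dscam, Fam129a, Gria4, Iars, Kcnb2, Npas2, Ntng1, Nupr1, Rims2, Sesn2, Slc7a1, Slc7a3 and Unc13b). Within cluster 5 alone Slc32a1 (-0.09) and Ntf3 (-0.69) turned and within clusters 3 and 4 alone Ern1 (-0.74), Nr4a1 (-7.81), Npas2 (-0.04), Tsc22d3 (-0.33) and Ntf3 (-1.86) did. Clusters 3 and 4 held only 25 and 62 mKI nuclei, and these values did not pass there (edgeR adjusted p between 0.627 and 0.994). Their size, that of Nr4a1 above all, is therefore no measure of a change. Without mKI 1 Chst7 was -2.95, and Emilin3, Col27a1, Tgm5 and Dnm3os had 0 mKI counts left. Granule marker genes other than Gabra6 stood at 1800, 1815, 1030 and 1196 CPM in this class, and olfactory and striatal markers at 2037, 2037, 1782 and 3457.

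Within granule cluster 5, Fam129a (log2 4.37, adjusted p = 0.0404), Cars (3.33, 0.0391), Slc7a1 (2.53, 0.0464), Bdnf (3.15, 0.0391) and Kcnb2 (1.70, 0.0237) rose, and Syt1 (-1.22, 0.0232) and Ntng1 (-1.55, 0.0276) fell. These 7 of 48 named genes kept the call there, with 86, 49, 1590 and 538 nuclei. List medians inside the cluster were 2.33 for the stress response (21 genes, camera adjusted p = 1.02e-22; adjusted p = 0.811 with an estimated correlation) and 1.05 for the synthetases (20 genes, 1.13e-11; 0.985 estimated). Within clusters 3 and 4, 23 of 54 kept it, among them Slc7a3 (5.85), Nupr1 (5.09), Atf5 (4.56) and Ccnd2 (5.30), with 4154, 3554, 25 and 62 nuclei.

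Molecular layer interneurons of the cerebellum changed in 139 genes of 10159 tested (89 rose and 50 fell, edgeR; DESeq2 called 61). Fam129a rose from 0 counts in both wild-type libraries (at least 43.5-fold higher, adjusted p = 0.00740), as did the collagen receptor gene Ddr2 (at least 21.0-fold, 0.0109) and Trib3, a pseudokinase induced by ATF4 (at least 20.5-fold, 0.0109). Slc7a3 had a count ratio of 48.0 (interval 12.7 to 405) and Nupr1 of 22.5 (5.70 to 194). The mitochondrial folate genes Aldh1l2 (5.31-fold, log2 2.41, SE 0.29, 0.00821) and Mthfd2 (4.11-fold, 2.04, SE 0.27, 0.0109) rose with Sesn2 (2.95), and the synthetase genes Aars (1.65), Sars (1.53), Yars (1.49) and Gars (1.28) rose. Ccnd2 (7.74-fold, 2.95, SE 0.36, 0.00942), the AMPA receptor gene Gria1 (4.83-fold), and the potassium channel genes Kcnb2 (1.72), Kcnh7 (1.78), Kcnq5 (1.64) and Kcnc2 (2.48) rose. So did the guidance genes Robo2 (1.64), Slit3 (1.84) and L1cam (1.31) and the clock gene Npas2 (1.84). Falls were seen in Col12a1 (-3.56, SE 0.57, 0.0153), the proteoglycan gene Vcan (-2.46), the monoamine transporter gene Slc18a2 (-2.46), Sema3e (-1.27), Homer3 (-1.38), Grm8 (-0.97) and Shank2 (-0.91). Few counts remained of Pip5k1bos (ratio 0.0468, 0.00115 to 0.280) and of the antioxidant regulator Nfe2l2 (0.105, 0.0208 to 0.327). Of 31 named genes, 14 lost the call without wild type 1 (adjusted p up to 0.540), 11 without wild type 2 (up to 0.426) and 11 of 26 without mKI 1 (up to 0.540), 30 of 30 with nuclei classed by marker score and 20 of 20 when thinned. The call of 8 (Aldh1l2, Ccnd2, Gria1, Kcnb2, Kcnh7, Mthfd2, Robo2 and Sema3e) held without each library. Without wild type 1 and without wild type 2 in turn, log2 values moved to 1.75 and 3.1 for Gria1, 1.94 and 3.29 for Kcnc2 and 1.35 and 2.46 for Slit3. Slc7a3 (4.28) and Nupr1 (3.23) moved without wild type 1, which had 0 counts of either. Without mKI 1 the values were -1.79 for Nfe2l2, -1.52 for Vcan and 1.81 for Aldh1l2, and Pip5k1bos and Col12a1 had 0 mKI counts left. The genes called were 79, 89, 152 and 1075 with each library left out in turn, and olfactory and striatal markers stood at 1040, 1064, 1703 and 1921 CPM.

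Dentate granule neurons of the hippocampus gained Slc1a4, a neutral amino acid transporter (16.5-fold, log2 4.05, SE 0.49, edgeR adjusted p = 0.0321; 3.24, 3.97, 57.4 and 75.8 CPM), and Aars, alanyl-tRNA synthetase (5.40-fold, 2.43, SE 0.31, 0.0321; 17.8, 21.8, 108 and 111 CPM). These were the only 2 of 8093 genes past the threshold (556 at unadjusted p under 0.05, DESeq2 5). Values short of the threshold were 2.34 for Cars, -1.77 for the adhesion gene Cntn3 and -1.73 for Zfp804b (adjusted p = 0.0648 each). Both calls were lost without wild type 2 (adjusted p = 0.244), thinned (0.148) and by marker score (0.130 and 0.181), and 9, 0, 274 and 322 genes were called with each library left out in turn.

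In glutamatergic neurons Gabra6, a subunit made by cerebellar granule cells, fell (log2 -4.08, SE 0.23, edgeR adjusted p = 0.0193; 46.4, 56.6, 3.23 and 2.81 CPM), the only call of 14733 genes (733 at unadjusted p under 0.05, DESeq2 61). In GABAergic neurons Gabra6 fell as well (-3.78, SE 0.39, 0.0143; 52.8, 58.5, 5.07 and 1.65 CPM), the only call of 11046 genes (450 at unadjusted p under 0.05, DESeq2 3). Other values in glutamatergic neurons were -2.95 for Fat2, -3.41 for Cbln3, -1.97 for Ror1 and -2.09 for Il16, and in GABAergic neurons -3.54 for Fat2, -4.07 for Cbln1, -2.35 for Zic1 and -1.61 for Tmem163. Fat2, Cbln1, Cbln3 and Zic1 are likewise cerebellar granule genes, and Gabra6 stood at 769, 888, 267 and 341 CPM in granule neurons, which were the more abundant in wild type. The Gabra6 call was lost without wild type 1 (adjusted p = 0.116 in glutamatergic and 0.449 in GABAergic neurons) and without wild type 2 (0.260 and 0.807), and when thinned (0.0788 and 0.105), in glutamatergic neurons with doublets kept (0.0812) and in GABAergic neurons by marker score (0.238). With the replicate number as a block it was lost in glutamatergic neurons (edgeR adjusted p = 0.317) and kept in GABAergic neurons. Without mKI 1 the Gabra6 value was -5.01 in GABAergic neurons. In these classes 988 and 163 genes were called without mKI 2, and 132 and 36 without mKI 1. Glutamatergic cluster 1 held 56.9% of wild-type and 28.2% of mKI glutamatergic nuclei.

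Among glia, Bergmann glia gained Zfp804b, a zinc finger gene (log2 5.08, SE 0.63, count ratio 41.1, interval 12.1 to 217, edgeR adjusted p = 0.0444), the only call of 5825 genes (554 at unadjusted p under 0.05, DESeq2 6). Values were 2.22 for Agbl4, -1.90 for Sgcd, 2.18 for Shroom3 and 2.78 for Col4a5. The Zfp804b call was lost with the replicate number as a block (edgeR adjusted p = 0.318). Astrocytes had 0 calls of 12131 genes (edgeR; 483 at unadjusted p under 0.05, DESeq2 0), with values of 3.23 for the opioid peptide gene Penk, 2.61 for Atf5 and 1.75 for Ptprn (adjusted p = 0.554). Count ratios there were 71.0 (12.1 to 2861) for Dlx6os1 and 51.7 (8.70 to 2102) for Top2a. Their intervals leave out the spread between libraries, and edgeR called neither gene. Oligodendrocytes had 0 of 10175 (541, DESeq2 10), with Grm7 at -1.57, Gabra6 at -2.41, Pcp2 at -2.68, Mrgpra2b at -2.86 and Vgf at 2.68. Precursors had 0 of 8488 (417, DESeq2 5), with Kcnip4 at -1.64 (edgeR adjusted p = 0.0842), Galntl6 at 1.57, Gabra6 at -2.92, Slc24a2 at 1.38 and Caln1 at -1.32. Gabra6 and Pcp2 are markers of cerebellar granule and Purkinje neurons. Granule markers other than Gabra6 stood at 276, 241, 115 and 120 CPM in oligodendrocytes and 340, 318, 216 and 225 in precursors. Microglia had 0 of 7842 (237, DESeq2 6), with Tenm4 at 3.59, Nxph1 at 2.64, Gria1 at 2.45, Svep1 at -3.08 and Dlgap2 at 2.97, most of them genes of neurons. Without mKI 1 and without mKI 2 the calls were 190 and 149 in Bergmann glia, 358 and 666 in astrocytes, 199 and 759 in oligodendrocytes, 18 and 42 in precursors, and 489 and 586 in microglia. Without wild type 1 and without wild type 2 they were 4 and 5 in Bergmann glia, with Zfp804b not among them (adjusted p = 0.998 and 1.0; 0.109 by marker score), 2 and 5 in precursors, and 0 in the others.

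Endothelial cells gained Atf5 (17.6-fold, log2 4.14, SE 0.40, edgeR adjusted p = 0.0184) and Egfem1, an EGF-domain gene (9.05-fold, 3.18, SE 0.30, 0.0184), the only 2 of 10433 genes (1029 at unadjusted p under 0.05, DESeq2 41). Values there were -3.81 for Rnf182, 2.77 for the prostacyclin synthase gene Ptgis and 3.49 for Eif4ebp1. In pericytes and smooth muscle cells 13 genes rose and 1 fell of 8069 (695 at unadjusted p under 0.05, DESeq2 10). The rises included the endothelin receptor gene Ednrb (26.6-fold, 4.73, SE 0.49, 0.00486), Atf5 (13.9-fold, 3.80, SE 0.37, 0.00486), Eif4ebp1 (9.85-fold, 3.30, SE 0.53, 0.0426) and Ccnd2 (5.18-fold, 2.37, SE 0.31, 0.0208). Trib3 (count ratio 59.6, 10.1 to 2418), Trim66 (61.2, 10.3 to 2481) and Asns (31.4, 8.13 to 269) rose from few counts, and Spp1, osteopontin, fell (-3.31, SE 0.46, 0.0254; 126, 125, 11.9 and 12.4 CPM). In meningeal fibroblasts the imprinted gene Nnat fell (-2.21, SE 0.21, 0.0143; 1807, 1472, 400 and 309 CPM), the only call of 9138 genes (614 at unadjusted p under 0.05, DESeq2 6). Other values were 3.17 for Hhip, 2.75 for Meis2, -1.37 for Atp13a5 and -1.59 for Gpc5. With the replicate number as a block, 7 of the 9 named pericyte genes lost the call. All 9 named pericyte genes lost the call without mKI 1 (adjusted p = 0.484), 5 with DESeq2, 5 with doublets kept, 8 of 8 by marker score and 4 of 4 when thinned. There 66, 76, 0 and 118 genes were called with each library left out in turn; in endothelial cells these counts were 17, 43, 547 and 360 and in meningeal fibroblasts 25, 16, 243 and 359. Without wild type 1 and without wild type 2 in turn, log2 values moved to 6.35 and 4.10 for Ednrb in pericytes and 4.98 and 3.58 for Atf5 in endothelial cells. Trib3 was 4.48 and Trim66 4.39 without wild type 1, which had 0 counts of either. Egfem1 lost the call with doublets kept (adjusted p = 0.528), all barcodes (0.118) and thinned (0.191), Nnat with doublets kept (0.123), and by marker score Egfem1, Atf5 and Nnat all did (between 0.143 and 0.569). Hemoglobin transcripts stood at 3014, 267, 35.2 and 154 CPM in pericytes and at 1172, 586, 45.5 and 3612 CPM in endothelial cells.

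Genes of energy and protein synthesis were lower in part of the classes. Nuclear-encoded oxidative phosphorylation genes were lower in 5 of 13, with medians of -0.35 in endothelial cells (camera adjusted p = 1.06e-06; adjusted p = 0.980 with an estimated correlation, as for every list that follows), -0.34 in molecular layer interneurons, -0.31 in microglia, -0.18 in oligodendrocytes and -0.17 in meningeal fibroblasts. Cytosolic ribosomal proteins were lower in 6 of 13 (microglia -0.29, GABAergic neurons -0.21, oligodendrocytes -0.20, endothelial cells -0.16, meningeal fibroblasts -0.15 and glutamatergic neurons -0.14) and higher in pericytes (0.43, 79 of 79 genes positive). Mitochondrially encoded genes were lower in GABAergic neurons (-0.34) and pericytes (-0.29). Cholesterol synthesis genes were lower in astrocytes (-0.48, adjusted p = 5.93e-06), glutamatergic neurons (-0.38, 3.40e-06; 16 of 22 genes lower in both mKI libraries) and GABAergic neurons (-0.34). Without mKI 1 the ribosomal medians turned to 0.34 in microglia, 0.38 in GABAergic neurons, 0.36 in oligodendrocytes, 0.19 in endothelial cells, 0.36 in meningeal fibroblasts and 0.53 in glutamatergic neurons. The oxidative phosphorylation medians turned to 0.25 in molecular layer interneurons, 0.20 in oligodendrocytes, 0.09 in microglia and 0.18 in meningeal fibroblasts, and the endothelial one was -0.11 without mKI 1 (adjusted p = 0.265) and -1.08 without mKI 2. The pericyte ribosomal median was -0.12 without mKI 2, the GABAergic mitochondrial median 0.50 and the pericyte one -0.053 without mKI 1 (-0.92 without mKI 2), and the astrocyte cholesterol call was lost without mKI 2 (adjusted p = 0.057). The cholesterol median was -0.62 without mKI 1 and -0.20 without mKI 2 in GABAergic neurons, and -0.24 without wild type 2 in astrocytes. Only the cholesterol call in glutamatergic neurons held without each library in turn.

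Lists of synapse, growth and glial genes passed in part of the classes, with no test of the difference between classes. Presynaptic vesicle release genes were lower in 6 of 13 classes (Bergmann glia -0.52, endothelial cells -0.44, pericytes -0.30, microglia -0.29, dentate granule neurons -0.16 and precursors -0.14). In these classes, as in most others, granule neuron markers other than Gabra6 were also lower in both mKI libraries. They stood at 609, 510, 401 and 310 CPM in Bergmann glia and 403, 672, 201 and 151 in endothelial cells. How much of the presynaptic change granule transcripts make was not tested. Glutamatergic postsynapse genes were higher in microglia (0.54, adjusted p = 1.37e-07; 0.980 estimated) and meningeal fibroblasts (0.10) and lower in dentate granule neurons (-0.15). GABAergic synapse genes were lower in pericytes (-0.39), axon guidance genes were higher in microglia (0.53) and astrocytes (0.29), and voltage-gated ion channels passed in 0 of 13. Immediate early genes were higher in 4 of 7 classes (granule neurons 1.24, pericytes 1.02, astrocytes 0.75 and meningeal fibroblasts 0.75). Neurogenesis genes were higher in granule neurons (1.05), and cell cycle genes in pericytes (0.77), granule neurons (0.54), endothelial cells (0.50) and astrocytes (0.21). Myelin genes were higher in granule neurons (0.57), microglia (0.55), precursors (0.52, adjusted p = 4.91e-07; 0.980 estimated) and endothelial cells (0.38), and reactive astrocyte genes in astrocytes (0.48, 1.61e-05; 0.980 estimated), where 3 of 11 passed adjusted over the list alone. Interferon response genes were higher in pericytes (0.62), astrocytes (0.35) and endothelial cells (0.31), and neurotrophin and insulin-like growth factor genes in pericytes (0.06, mean 0.71, adjusted p = 0.0484). Heat shock chaperones (-0.35) and glucocorticoid response genes (-0.49, adjusted p = 0.00156) were lower in oligodendrocytes, turning to 0.01 and 0.19 without mKI 1. The unfolded protein response (median over classes 0.07), p53 targets (0.11), mTOR pathway (0.03), circadian clock (-0.02), homeostatic microglia (-0.0045) and disease-associated microglia (0.23) lists passed in no class. In granule neurons the immediate early and neurogenesis calls were lost without mKI 2 (adjusted p = 0.25 and 0.44) and turned in cluster 5 alone (-0.57 and -0.32). In all, 82 of 369 class and list pairs passed, all nuclei included (53 higher and 29 lower), and 0 with an estimated correlation. Of these, 31 lost the call without wild type 1, 16 without wild type 2, 16 without mKI 1 (with 16 more turned) and 24 without mKI 2 (with 2 more turned). Of the calls in this paragraph only presynaptic genes in Bergmann glia, axon guidance genes in astrocytes and myelin genes in precursors held without each library in turn, with the astrocyte median at 0.094 without mKI 1 and the precursor median at 0.32 without mKI 2. Without mKI 1 and without mKI 2 in turn, medians were 0.011 and 1.63 for endothelial myelin genes, 0.023 and 0.46 for meningeal glutamatergic postsynapse genes, 0.40 and 0.77 for endothelial cell cycle genes and 0.95 and 0.24 for pericyte interferon genes. Without mKI 2 granule medians were 0.29 for neurogenesis, 0.43 for immediate early and 0.39 for myelin genes, the last 0.92 without wild type 1. Also without mKI 2 the medians were -0.16 for pericyte GABAergic synapse genes, 0.84 for reactive astrocyte genes and 1.21 for meningeal immediate early genes. Dentate glutamatergic postsynapse and presynaptic medians were -0.30 and -0.33 without mKI 1. The astrocyte interferon median was 0.14 without mKI 1 and 0.66 without wild type 1, and the astrocyte cell cycle median 0.42 without wild type 2. Without wild type 1 and without wild type 2 in turn, the presynaptic median was -0.037 and -0.20 in precursors and -0.71 and -0.24 in endothelial cells. In microglia glutamatergic postsynapse (-0.11) and axon guidance (-0.31) medians turned without mKI 1 and the presynaptic median (0.14) without mKI 2, while olfactory and striatal neuron markers stood there at 1219, 1007, 2092 and 1172 CPM. In pericytes the immediate early median turned to -0.054 without mKI 2, and without wild type 2 the cell cycle median turned to -0.26 (0.33 without mKI 1) and the neurotrophin median to -0.069 (0.24 without mKI 2).

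**Figure D4:**
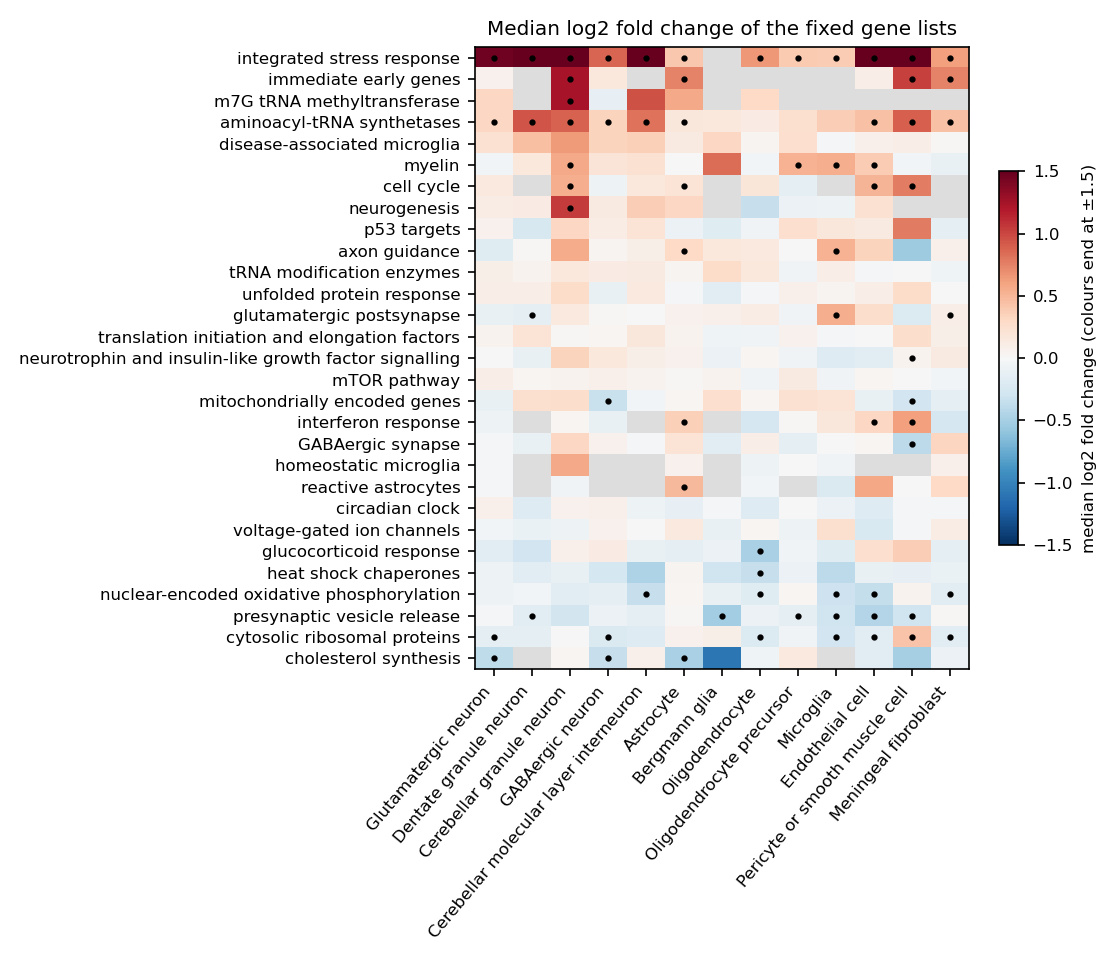
Median log2 fold change (mKI over wild type) of each gene list (rows) in each class (columns), with dots where camera adjusted p was under 0.05 and grey where a list was not tested. The integrated stress response and synthetase lines are higher across most classes, and colours end at 1.5 in each direction.

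With all nuclei of a library added together, 0 of 18640 genes passed (edgeR, smallest adjusted p 0.0540; 3350 at unadjusted p under 0.05, DESeq2 1273). The smallest p-values belonged to Gabra6 (log2 -3.94), Ptpn22 (-3.35), Crtam (-3.66), the granule-cell transcription factor gene Neurod1 (-3.26) and Tll1 (-2.20), in libraries whose granule share was 50.2, 38.4, 12.1 and 7.31%. The stress response list was higher in this sum (1.13, adjusted p = 1.18e-12; adjusted p = 0.980 with an estimated correlation), with 19 of 29 genes adjusted over the list alone, and the synthetases were too (0.27, 9 genes; adjusted p = 0.980 with an estimated correlation). Oxidative phosphorylation (-0.37), ribosomal protein (-0.28) and presynaptic (-0.17) genes were lower, and immediate early (1.03), neurogenesis (0.60), glutamatergic postsynapse (0.57), homeostatic microglia (0.51), axon guidance (0.46) and GABAergic synapse (0.26) genes higher, each at adjusted p = 0.980 with an estimated correlation. The sum does not separate changes within nuclei from changes in the shares of the classes. Microglia made up 1.23, 1.34, 3.21 and 2.46% of kept nuclei, and homeostatic microglia genes passed in no class (median over classes -0.0045). The ribosomal median was 0.29 without mKI 1 and -1.43 without mKI 2, the oxidative phosphorylation median -0.077 and -0.97, the presynaptic median -0.32 and -0.020 and the homeostatic microglia median 0.80 and 0.30. The immediate early median was 0.67 without mKI 1 and the glutamatergic postsynapse median 0.34 without wild type 1. Of the lists other than the stress response and the synthetases, immediate early genes alone held the call without each library in turn. Without mKI 2 the sum had 1829 genes called and without each other library 0.

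The genotype effect was compared between classes gene by gene. Cerebellar granule neurons exceeded glutamatergic neurons in 25 of 27 stress response genes, with a median difference of 1.11 in log2, but 0 of 13647 genes passed (limma, smallest adjusted p 0.0582; 1952 at unadjusted p under 0.05, DESeq2 not run on differences), a pair chosen after the class results were seen. The difference was 4.31 for Slc7a3 (adjusted p = 0.110), 4.39 for Fam129a (0.0653) and 2.19 for Sesn2 (0.0968). Of the 3 pairs planned beforehand, glutamatergic against GABAergic neurons gave 0 of 10983 genes (434 at unadjusted p under 0.05), against oligodendrocytes 0 of 10009 (578) and against astrocytes 0 of 11685 (514). On simulated data this test recovered at most 1.56% of 4-fold differences, so 0 calls do not show that the classes responded alike. Without wild type 2 the first pair had 201 calls, and with a minimum count of 30 granule against glutamatergic neurons had 158.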

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

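The tests of this part were chosen after the class results were seen. Of the 7 clusters that no class took, which enter the sum of all nuclei but no class comparison, clusters 7, 11 and 24 had 20 nuclei in every library and were tested, and the integrated stress response list was called higher in these 3. Clusters 6, 16, 22 and 32 were not tested. In cluster 7 the list median was 1.32 in log2 (8 genes, 8 higher in both mKI libraries than in both wild-type libraries, 5 adjusted over the list alone, camera adjusted p = 2.15e-04; adjusted p = 0.744 with an estimated correlation). In cluster 11 it was 0.53 (18 genes, 12 higher in both, 4 adjusted over the list alone, adjusted p = 7.76e-10; 0.744 estimated). In cluster 24 it was 1.16 (18 genes, 17 higher in both, 8 adjusted over the list alone, 2.59e-19; 0.744 estimated). Each was put forward because it is a signal in nuclei that the report's class comparisons do not use. In cluster 7 Igf1, insulin-like growth factor 1 (log2 3.33, SE 0.35, edgeR adjusted p = 0.0197), Deptor, an mTOR inhibitor (3.11, 0.0114), Meis2 (4.99, 0.0375) and Cck (2.93, 0.0375) rose among 22 genes, and 3 fell, of 6448 tested (869 at unadjusted p under 0.05, DESeq2 75). In cluster 11 Gabra6 alone passed (-3.42, edgeR adjusted p = 0.0264, 12512 tested, DESeq2 39), at 39.5, 43.8, 3.73 and 4.19 CPM. It is a subunit made by cerebellar granule cells, and it fell likewise in glutamatergic and GABAergic neurons. In cluster 24 0 of 11374 passed (635 at unadjusted p under 0.05, DESeq2 16).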

How the results depend on the processing

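The alternatives were fixed before the data were examined, apart from those said to be added later. Shares of nuclei stayed on their side of the threshold in 17 of 17 classes with doublets kept and 18 of 18 with all deposited barcodes and resolution 2. The 124 named values cover the called genes and, outside granule neurons and all nuclei, Wdr4 and Mettl1, which had no call there. A value without a call that stayed without one is counted as unchanged, so these are not counts of calls kept. Granule Mettl1, whose lost calls are given above, is not among them. With DESeq2 106 kept their side of the threshold and their direction (18 lost the call). With RLE factors 123 did, with no low-count filter 89 and with the replicate number as a block 99. The counts were 49 of 104 by marker score, 48 of 90 thinned, 96 of 108 with doublets kept and 104 of 109 with all barcodes. Calls lost with a library left out are given with each class above. With a library left out, the lone library of its genotype was assumed to vary like the other group. The cause of a change was not tested unless stated. On simulated data 2.06% of 4-fold changes were recovered in microglia and between 64.6 and 87.8% elsewhere.

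Counts of genes called by DESeq2 were 1273 in all nuclei, 61 in glutamatergic neurons, 5 in dentate granule neurons, 3 in GABAergic neurons, 61 in molecular layer interneurons, 6 in Bergmann glia, 10 in oligodendrocytes, 5 in precursors, 6 in microglia, 41 in endothelial cells and 6 in meningeal fibroblasts. With no low-count filter they were 149 in all nuclei, 186 in glutamatergic, 75 in dentate granule, 129 in cerebellar granule and 28 in GABAergic neurons, 429 in molecular layer interneurons, 108 in astrocytes, 77 in Bergmann glia, 128 in oligodendrocytes, 36 in precursors, 72 in microglia, 10 in endothelial cells, 159 in pericytes and 98 in meningeal fibroblasts, and Mettl1 in granule neurons was 1.60. Thinned, with fewer counts, they were 4 in all nuclei, 4 in molecular layer interneurons, 2 in meningeal fibroblasts, 1 in precursors, 1 in endothelial cells and 0 in glutamatergic, dentate and GABAergic neurons, Bergmann glia and pericytes, and Wdr4 in meningeal fibroblasts turned to -0.31. With doublets kept they were 0 in glutamatergic neurons, 349 in astrocytes, 1 in endothelial cells, 5 in pericytes and 0 in meningeal fibroblasts. No cluster was named Bergmann glia there, so that class gave no value, and the astrocyte class held 937, 879, 267 and 882 nuclei against 577, 541, 170 and 693. With all deposited barcodes they were 277 in molecular layer interneurons, 6 in endothelial cells and 58 in pericytes, and with RLE factors 2 in Bergmann glia. By marker score they were 1 in dentate granule neurons and 0 in GABAergic neurons, molecular layer interneurons, Bergmann glia, endothelial cells, pericytes and meningeal fibroblasts, the share of 2 classes passed, molecular layer interneuron nuclei turned to 0.28, and the ratio of neurons to other nuclei was 0.040.

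With the replicate number as a block, counts were 0 in glutamatergic neurons, 24 in dentate granule neurons, 3 in GABAergic neurons, 0 in Bergmann glia, 120 in endothelial cells and 2 in pericytes; libraries of the same number share only a number, and their deviations correlated at -0.34 in all nuclei and -0.20 in granule neurons. With the pairing crossed, added after seeing the data, counts were 14 in glutamatergic neurons, 0 in dentate granule neurons, 2 in GABAergic neurons, 76 in Bergmann glia, 3 in oligodendrocytes, 1 in precursors, 106 in endothelial cells, 25 in pericytes and 16 in meningeal fibroblasts.

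Also added after seeing the data, granule cluster 5 alone called 29 genes, with Mettl1 at 0.79, Slc32a1 at -0.091, Ntf3 at -0.69, immediate early genes at -0.57 and neurogenesis genes at -0.32. Granule clusters 3 and 4 alone called 310, with Ern1 at -0.74, Nr4a1 at -7.81, Npas2 at -0.041, Tsc22d3 at -0.33 and Ntf3 at -1.86. None of these named values passed there, with 25 and 62 mKI nuclei. With granule transcripts left out, Gabra6 among them by construction, 0 genes were called in glutamatergic and GABAergic neurons, 2 in Bergmann glia and 4 in meningeal fibroblasts. With granule nuclei left out of the total, nuclei of oligodendrocytes turned to -0.10 and of precursors to -0.60, and with unnamed nuclei left out the ratio of neurons to other nuclei was -0.13. With an estimated correlation 0 lists passed, and 0 classes had the stress response or the synthetase list higher, with granule cluster 5 alone as well. With a minimum count of 30, granule against glutamatergic neurons gave 158 genes.

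With each library left out in turn, genes called ranged from 0 to 1829 in all nuclei, 0 to 988 in glutamatergic neurons, 0 to 322 in dentate granule neurons, 115 to 3825 in cerebellar granule neurons, 0 to 163 in GABAergic neurons, 79 to 1075 in molecular layer interneurons, 0 to 666 in astrocytes, 4 to 190 in Bergmann glia, 0 to 759 in oligodendrocytes, 2 to 42 in precursors, 0 to 586 in microglia, 17 to 547 in endothelial cells, 0 to 118 in pericytes, 16 to 359 in meningeal fibroblasts and 0 to 201 for glutamatergic against GABAergic neurons. Wdr4 ranged from -0.039 to 0.55 in glutamatergic, 0.69 to 0.88 in granule and -0.72 to 0.21 in GABAergic neurons, -0.39 to 0.67 in oligodendrocytes, -0.19 to 0.16 in precursors and -0.31 to 0.77 in meningeal fibroblasts, and Mettl1 from 1.49 to 1.84 in granule neurons, -0.77 to 1.73 in GABAergic neurons and -1.44 to 0.45 in microglia. Between 0 and 1 classes passed for nuclei, whose log2 values ranged from -1.94 to 0.032 in molecular layer interneurons, -0.18 to 4.0 in thalamic neurons, -2.78 to 0.30 in pericytes, -2.30 to 0.42 in astrocytes, -1.06 to 0.27 in meningeal fibroblasts, -2.94 to 0.57 in endothelial cells and -0.33 to 0.46 in precursors. Between 62 and 143 lists passed. Ribosomal medians ranged from -1.43 to 0.29 in all nuclei, -1.20 to 0.53 in glutamatergic and -0.81 to 0.38 in GABAergic neurons, -1.02 to 0.36 in oligodendrocytes, -1.24 to 0.34 in microglia, -1.08 to 0.19 in endothelial cells, -0.12 to 0.97 in pericytes and -1.06 to 0.36 in meningeal fibroblasts. Oxidative phosphorylation medians ranged from -0.53 to 0.25 in molecular layer interneurons, -0.70 to 0.20 in oligodendrocytes, -0.76 to 0.090 in microglia and -0.83 to 0.18 in meningeal fibroblasts, mitochondrially encoded from -1.64 to 0.50 in GABAergic neurons, heat shock from -1.01 to 0.0099 and glucocorticoid from -1.74 to 0.19 in oligodendrocytes, and in microglia glutamatergic postsynapse from -0.11 to 0.85, presynaptic from -0.93 to 0.14 and axon guidance from -0.31 to 1.11.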

Other observations

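Olfactory bulb granule neurons, striatal projection neurons and thalamic or midbrain neurons were too few in some libraries for gene tests. Their shares of kept nuclei were 1.10, 0.128, 4.6 and 11.5%, 0, 2.09, 6.69 and 5.45%, and 0.106, 1.95, 2.25 and 1.19%. Genes of olfactory and striatal neurons stood at 1219, 1007, 2092 and 1172 CPM in microglia, 823, 919, 1119 and 1241 in astrocytes, 463, 683, 942 and 929 in oligodendrocytes and 1248, 1207, 1680 and 1904 in dentate granule neurons.

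For the integrated stress response in mKI nuclei, the ratio of the thinned to the unthinned median was planned before the values were seen, and the other 3 tests after. With the counts of each class thinned to those of its smallest library, not matched per nucleus, the median over classes was 0.730 of its value (0.85 against 1.16), between the bounds set beforehand of 0.5 and 0.75, so that test left depth open; thinning left a median of 8.5 list genes per class. On the same genes, a test chosen after seeing this, the ratio was at least 0.75 in 10 of 12 classes. Random thinning leaves the expected proportions of the genes unchanged, so this ratio cannot decide on depth, which stays open. Without the deeper mKI 1 the median was 1.07 times its value, which does not point to that library alone. Heat shock chaperones had a median at or below 0 in 12 of 13 classes and 0 were called higher, but immediate early genes were called higher in 4 of 7, so stress of handling could not be told from the mutation.

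For granule neurons, the test on the other called genes was planned before the values were seen, and the test on the stress response after. The mKI granule nuclei lay in cluster 5 and the wild-type ones in clusters 3 and 4. Within cluster 5 the stress response median was 0.847 of its value on the same 21 genes (2.33 against 2.75), so it may hold in granule neurons of 1 cluster. The other called genes kept 0.646 of their signed median (0.87 against 1.35). Since 96.1% of mKI granule nuclei stand in both comparisons and no value without a change was computed for either ratio, how much of the change lies between clusters is left open.

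For the smaller share of granule nuclei, both tests were chosen after seeing the shares. In 3 of 3 classes outside the cerebellum (olfactory bulb, striatal and thalamic or midbrain) the larger gap in share within a genotype was over 0.5 of that between genotypes: 3.05 against 4.25 and 4.12 against 1.81 in log2 for olfactory bulb and thalamic or midbrain neurons, which alone meet the bound of 2 classes, with 0.73 against 2.22 for granule neurons. For striatal neurons, with 0 nuclei in wild type 1, the gaps were at least 5.88 and 4.47, taken at the upper limit of that share. Libraries that hold different parts of the brain could thus account for it. Of Purkinje neurons, Bergmann glia and molecular layer interneurons, 0 had a ratio to granule nuclei that separated the genotypes by over 2 times the gap within one (0.17 against 1.54, -0.22 against 1.60 and 1.27 against 1.24). Whether the mKI cerebellum is smaller or was sampled less could not be told.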
